A study of Homo sapiens with 15 samples.

How the data were processed

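RNA was sequenced from atrial cardiomyocytes made from H7 cells, an established human embryonic stem cell line, in 15 libraries that fell into 5 groups of 3. Per the labels' protocols, the cells were directed to the atrial fate with a retinoid, and spheroids were dissociated at day 17. The groups were cells given a scramble siRNA, a first siRNA against ATRNL1 (siRNA-1), a second siRNA against ATRNL1 (siRNA-2), a control lentivirus, or a lentivirus carrying the short isoform of ATRNL1, with puromycin selection of the lentiviral cells. The growth protocol in the labels breaks off before its end, so the days of treatment and harvest are not given in the sources used here. Per the labels' protocols, libraries were made after ribosomal RNA depletion and sequenced on a NovaSeq, whereas the molecule field of the labels names polyA RNA. This bears on transcripts without a polyA tail, such as most histone mRNAs, whose level depends on the library type.

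The authors deposited 1 table of whole-number read counts per gene, with 59429 rows and a column per library, and no normalization. Per the submitters' processing notes, STAR 2.7.9a, DESeq2 1.30.1 and the human genome build GRCh 38 were used, with no role given for each. The program that counted reads, its use of strand and any read filter are not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. The column names gave each library's group but not which of the group's labelled samples it was. Libraries were therefore used as replicates of their group, and their numbers below follow the order of the columns and pair nothing. Gene identifiers were those of GENCODE release 29 in 58780 rows, of which 58252 had a current symbol in the gene table used here. The other 649 rows carried a bare number in place of an identifier. They held 0.00157% to 0.00437% of a library's counts and were left out of library sizes and tests. Nothing in the labels says that the libraries came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

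Total counts ran from 37078568 to 108663135 per library. Genes were kept with edgeR's filterByExpr by group, which left 24659 genes. Libraries were scaled with TMM factors, and 1 quasi-likelihood model of 5 group means was fitted over all 15 libraries in edgeR 4.0.16 under R 4.3.3, so that the groups shared the estimate of the spread. The biological coefficient of variation was 8.24% and the prior degrees of freedom 14.5. Genes were called at a Benjamini-Hochberg adjusted p under 0.05 over all genes tested. Every adjusted p given for a single gene comes from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The standard error (SE) of a log2 fold change is its size divided by the square root of the test's F. Levels are counts-per-million values (CPM) with TMM-scaled library sizes, as mean ± SD over 3 libraries. The contrasts were each siRNA against scramble, the mean of both siRNAs against scramble, siRNA-1 against siRNA-2, ATRNL1 lentivirus against control lentivirus, and the overexpression effect minus the mean knockdown effect.

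The 40 gene lists were fixed before the data were examined, as were the tests, most alternatives and the rule for named genes. For heart muscle they were the sarcomere, atrial identity, ventricular identity, pacemaker identity, action potential ion channels, calcium handling, intercalated disc and desmosome, cardiac transcription factors, atrial fibrillation locus genes, natriuretic and hypertrophy genes, and the attractin family and partners. For stress and signalling they were the unfolded protein response, integrated stress response, heat shock response, oxidative stress response, p53 targets, apoptosis machinery, interferon response, NF-kB and cytokine response, immediate early genes, TGF-beta targets and extracellular matrix (called matrix genes), and NOTCH, WNT and hedgehog targets. For metabolism and growth they were hypoxia and glycolysis, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, nuclear-encoded oxidative phosphorylation, mitochondrially encoded mRNAs, lysosome and autophagy, cytosolic ribosomal proteins, cell cycle and replication-dependent histones. The rest were markers of fibroblasts, smooth muscle and pericytes, endothelium and endocardium, epicardium, neural cells, endoderm and liver, pluripotent cells and skeletal muscle. Some genes stand in several lists, with the most shared between the atrial fibrillation locus genes and the ion channels. Lists were tested with camera in limma 3.58.1 on voom values at a preset correlation of 0.01, again with an estimated correlation, and with Benjamini-Hochberg adjustment over the 40 lists of a contrast. Members are counted as called over all genes tested and again adjusted over the list alone.

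Genes named one by one followed a fixed rule. For each siRNA and for overexpression, called genes had to reach a mean of 1 CPM over the libraries compared and to have every treated library on the same side of every control library, and clone-named genes, pseudogenes and genes with an antisense, LINC, LOC, microRNA or small noncoding RNA symbol were left out. Long noncoding RNAs with a symbol of their own, such as BANCR, were kept. The 8 with the largest rise and the 8 with the largest fall were taken. For both siRNAs together, genes called in the same direction were ranked by the smaller of their changes and 10 were taken each way. For siRNA-1 against siRNA-2, 4 were taken each way, and for knockdown against overexpression 6 in each pairing of directions. Up to 4 members of a list with the smallest adjusted p stand as examples. Results of some list members are not reported here. ATRNL1 and its relative ATRN were always reported. Some of the genes taken lay below 1 CPM in every group, and most of these are not named.

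The alternatives were library size or relative log expression (RLE) scaling, other filters on low counts, only the groups compared in the fit, DESeq2 1.42.0, limma-voom, a log2 change of at least 1, an estimated correlation in camera, and leaving out each library in turn. Chosen after seeing the data were a single scramble library as the control and a fit without the 1 library of each group that looked most like a mix of the other 2. On simulated counts with 200 changed genes, the siRNA-1 comparison recovered 12% of genes changed 1.2-fold, 80% of those changed 1.5-fold and 98% of those changed 2-fold. There were 6 false calls among the unchanged of 24200 genes tested. In the simulated overexpression comparison the shares were 14% and 80% at the first 2 sizes, with 11 false calls among the unchanged of 24252 genes tested. These simulations drew genes independently, with 1 spread per gene for all groups. They leave out shifts common to many genes in a library and give no rate of false calls from such shifts. Scripts ran under Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.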

Results

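Gene expression was measured in human atrial cardiomyocytes derived from H7 embryonic stem cells in which ATRNL1 was lowered with either of 2 siRNAs or raised with a lentivirus, each beside its own control. ATRNL1 encodes attractin-like 1, a membrane protein related to attractin. There were 3 libraries per group. Total counts per library were 44584366, 56884016 and 107062380 for scramble, 50349548, 37078568 and 50972753 for siRNA-1 and 67006175, 60174197 and 48345838 for siRNA-2. They were 68931280, 108663135 and 46662214 for the control lentivirus and 98621378, 79237146 and 55976548 for the ATRNL1 lentivirus. The first principal component held 58.4% of the variance and parted the lentiviral libraries from the siRNA libraries. Each treatment was compared with the control of its own delivery method.

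ATRNL1 itself (ENSG00000107518, protein-coding, GRCh 38 chromosome 10, 115093365 to 115948992, plus strand) stood at 16.8, 13.8 and 15.3 CPM in the scramble libraries, 10.2, 9.02 and 8.26 CPM with siRNA-1, 4.93, 5.41 and 4.61 CPM with siRNA-2, 29.2, 27.5 and 27.1 CPM with the control lentivirus, and 636, 927 and 727 CPM with the ATRNL1 lentivirus. It fell by 40.1% with siRNA-1 (log2 fold change -0.74, SE 0.11, edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p = 8.95e-05) and by 67.3% with siRNA-2 (-1.61, SE 0.12, adjusted p = 9.57e-10). The siRNAs differed from each other by 0.87 (SE 0.12, adjusted p = 2.61e-05). The lentivirus raised ATRNL1 27.3-fold (log2 fold change 4.77, SE 0.12, adjusted p = 1.28e-19), a value that counts reads of the vector and of the cells' own gene together. ATRN, which encodes attractin (ENSG00000088812, chromosome 20, 3471040 to 3651122), stood at 155 ± 3.06 CPM in scramble (SD, n = 3) and fell to 126 ± 7.27 CPM with siRNA-1 (log2 fold change -0.30, SE 0.07, adjusted p = 0.00391) and 98.2 ± 1.86 CPM with siRNA-2 (-0.66, SE 0.07, adjusted p = 1.17e-07). The siRNA-1 call of ATRN ended, at -0.27, with scramble library 1 as the sole control. It rose from 157 ± 6.72 to 186 ± 14.0 CPM with overexpression (0.24, SE 0.07, adjusted p = 0.00586).

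**Figure D1:**
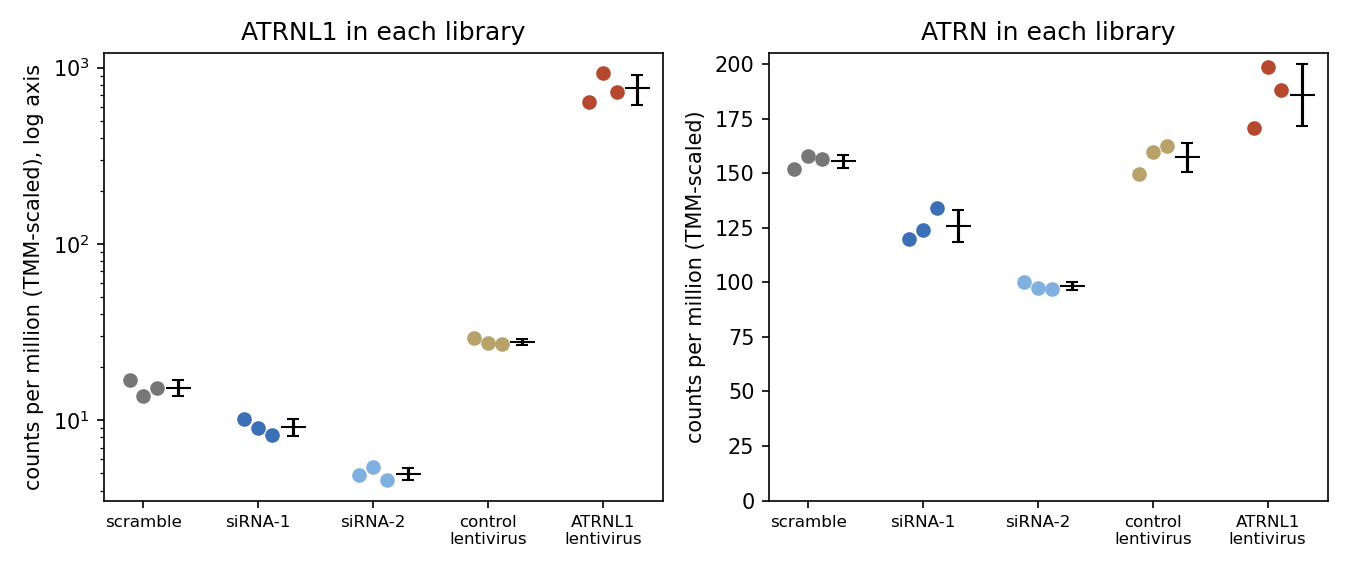
ATRNL1 on a log axis and ATRN on a linear axis from 0 in CPM for the 5 groups; each point is a library and each bar the mean ± SD of 3 libraries. ATRNL1 means were 15.3 CPM in scramble, 9.16 with siRNA-1, 4.99 with siRNA-2, 28.0 with the control lentivirus and 763 with the ATRNL1 lentivirus.

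The comparison of siRNA-1 with scramble asked which genes changed when ATRNL1 was lowered. Genes of the unfolded protein response, the programme that raises chaperones of the endoplasmic reticulum, were lower by camera at the preset correlation (adjusted p = 0.192 with an estimated correlation). HSPA5, the main chaperone of that compartment, fell from 1560 ± 644 to 583 ± 58.7 CPM (log2 fold change -1.42, SE 0.18, adjusted p = 7.14e-06), and HERPUD1, which acts in the degradation of misfolded proteins, from 169 ± 70.3 to 57.6 ± 4.97 CPM (-1.55, SE 0.18, adjusted p = 2.27e-06). With scramble library 1 as the sole control HSPA5 was at -0.64 and HERPUD1 at -0.78. The SEs and p-values of both genes rest on a spread shared by all 5 groups. They understate the spread of scramble, whose list mean had an SD of 0.50 log2 CPM, against 0.02 to 0.14 in the other groups. The limit reaches other genes compared with scramble. Over genes above 20 CPM, scramble libraries differed by an SD of up to 0.238 on the log2 scale. Within siRNA-1 it was at most 0.128 and within siRNA-2 at most 0.095. Genes of cholesterol synthesis (adjusted p = 0.0388 with an estimated correlation) and p53 targets (adjusted p = 0.174 with an estimated correlation) were also lower. MSMO1, an enzyme of cholesterol synthesis, fell by 0.89 on the log2 scale (SE 0.09, adjusted p = 2.28e-07) and CCNG1 by 0.61 (SE 0.09, adjusted p = 4.3e-05). In all, 1443 genes rose and 927 fell, 241 of these 2370 by at least 1 on the log2 scale.

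By list, 20 of 22 measured genes of the unfolded protein response fell with siRNA-1 and 0 rose (21 fell adjusted over the list alone). The median log2 fold change was -0.91 (camera adjusted p = 1.94e-26 and adjusted p = 0.192 with an estimated correlation). SDF2L1 fell by 1.96 and MANF by 1.28. The scramble libraries themselves stood apart in these genes, with mean log2 CPM of 6.22, 7.22 and 6.82, against 5.83 ± 0.09 with siRNA-1. Without scramble library 2 the median was -0.64 with 18 genes lower, and with scramble library 1 as the sole control it was -0.36 with 8 lower. Of 33 genes of the integrated stress response, 12 fell and 1 rose (16 and 1 adjusted over the list alone). Their median was -0.30 (camera adjusted p = 6.75e-08 and adjusted p = 0.645 with an estimated correlation). CHAC1, a glutathione-degrading enzyme, fell from 5.07 ± 0.363 to 1.29 CPM (-1.97, SE 0.17, adjusted p = 5.39e-08), and DDIT3, a stress-induced transcription factor, by 1.37. Scramble levels of this list were 4.34, 5.06 and 4.78, and with scramble library 1 as the sole control its median was 0.15. Among 25 p53 targets 15 fell and 0 rose (17 fell adjusted over the list alone). The median was -0.36 (camera adjusted p = 1.33e-13 and adjusted p = 0.174 with an estimated correlation), with MDM2 at -0.51 and CDKN1A at -0.52, 2 calls that ended at -0.41 and -0.35 with scramble library 1 as the sole control.

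Cholesterol synthesis was the 1 list of 17 called with siRNA-1 whose call held with an estimated correlation. Of its 24 genes 16 fell and 0 rose (18 fell adjusted over the list alone). Their median was -0.42 (camera adjusted p = 1.56e-20 and adjusted p = 0.0388 with an estimated correlation), with MSMO1 at -0.89, MVD at -0.85 and INSIG1 at -0.77. Of 15 genes of fatty acid synthesis 8 fell and 0 rose (9 adjusted over the list alone). The median was -0.26 (camera adjusted p = 1.06e-07 and adjusted p = 0.174 with an estimated correlation), with FASN, the fatty acid synthase, at -0.79. Mean log2 CPM of fatty acid synthesis genes ran from 5.95 to 6.24 in the scramble libraries, against 5.88 ± 0.08 with siRNA-1. Lysosome and autophagy genes held 7 that fell of 30 (7 adjusted over the list alone, camera adjusted p = 0.000596 and adjusted p = 0.629 with an estimated correlation). Oxidative stress genes held 2 of 18 (4 adjusted over the list alone, camera adjusted p = 0.0103 and adjusted p = 0.645 with an estimated correlation), and nuclear-encoded oxidative phosphorylation genes 3 of 40 (3 adjusted over the list alone, camera adjusted p = 0.00322 and adjusted p = 0.686 with an estimated correlation). With scramble library 1 as the sole control the lysosome and oxidative stress calls ended, with medians of -0.03 each against -0.11 and -0.12 before. The oxidative phosphorylation call ended there too (camera adjusted p = 0.0692), at a median of -0.05 with either control. The oxidative stress call also ended without scramble library 2 (median -0.06), and the oxidative phosphorylation call without siRNA-1 library 3 (-0.01).

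Of 38 cell cycle genes, 13 rose with siRNA-1 and 0 fell (20 rose adjusted over the list alone). Their median was 0.25 (camera adjusted p = 1.9e-09 and adjusted p = 0.629 with an estimated correlation). The examples were subunits of the replicative helicase, MCM6 (0.58, SE 0.09, adjusted p = 6.39e-05), MCM2 (0.53) and MCM5 (0.49), of which MCM2 and MCM5 lost their calls, at 0.41 and 0.28, with scramble library 1 as the sole control. The list's mean log2 CPM was 4.49, 3.94 and 4.25 in the scramble libraries and 4.46 to 4.48 with siRNA-1, and with scramble library 1 as the sole control its median was -0.01. Histone genes, whose near-identical copies make single members uncertain, held 2 of 26 that rose and 0 that fell (3 rose adjusted over the list alone). Their median was 0.27 (camera adjusted p = 3.82e-05 and adjusted p = 0.672 with an estimated correlation), with scramble levels of 3.29, 2.44 and 3.00. Of 7 neural markers 3 rose (3 adjusted over the list alone). Their median was 0.49 (camera adjusted p = 0.0017 and adjusted p = 0.328 with an estimated correlation), with the clearest rises in GAP43, a growth cone protein (1.65, SE 0.13), and MAP2 (0.83, SE 0.09). The neural call ended with scramble library 1 as the sole control, where the median was 0.74 and 3 genes rose (camera adjusted p = 0.057). Ribosomal protein genes held 2 of 40 that rose (1 adjusted over the list alone). The median was 0.07 (camera adjusted p = 0.00598 and adjusted p = 0.735 with an estimated correlation), and the call ended without siRNA-1 library 1 (0.05). The histone call ended without scramble library 2 (0.07), and the histone median turned to -0.10 with scramble library 1 as the sole control.

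Among cardiac lists 5 were called with siRNA-1. Sarcomere genes held 7 of 28 that rose and 1 that fell (9 and 2 adjusted over the list alone). The median was 0.12 (camera adjusted p = 0.00618 and adjusted p = 0.731 with an estimated correlation). XIRP2, an actin-binding repeat protein, rose from 5.85 ± 3.29 to 31 ± 14.4 CPM (2.42, SE 0.28, adjusted p = 2.53e-06) and MYH7, a myosin heavy chain, by 0.49. Atrial identity genes held 4 that rose and 1 that fell of 22 (6 and 1 adjusted over the list alone). Their median was 0.11 (camera adjusted p = 0.0303 and adjusted p = 0.731 with an estimated correlation), with NPPA, which encodes atrial natriuretic peptide, at -0.62. Genes at atrial fibrillation loci held 9 that rose and 2 that fell of 40 (12 and 4 adjusted over the list alone). Their median was 0.10 (camera adjusted p = 0.00506 and adjusted p = 0.685 with an estimated correlation), with the calcium buffer CASQ2 at 1.01. Pacemaker identity genes held 3 of 12 that rose (5 adjusted over the list alone). The median was 0.27 (camera adjusted p = 0.00113 and adjusted p = 0.645 with an estimated correlation). Of 24 cardiac transcription factors 5 rose (6 rose and 1 fell adjusted over the list alone). The median was 0.09 (camera adjusted p = 0.0232 and adjusted p = 0.72 with an estimated correlation). Without scramble library 2 these 5 list calls ended, with medians of 0.01 for sarcomere, 0.04 for atrial identity, 0.03 for atrial fibrillation loci, 0.17 for pacemaker and 0.08 for cardiac transcription factors, and with scramble library 1 as the sole control the sarcomere and atrial identity medians turned to -0.09 and -0.05 while the calls of pacemaker (0.09), cardiac transcription factors (0.02) and atrial fibrillation loci (0.01) ended. Without siRNA-1 library 1 the calls of sarcomere (0.05), atrial identity (0.16) and cardiac transcription factors (0.06) ended, as did that of atrial identity without siRNA-1 library 2 (0.07).

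The 8 genes with the largest rise after siRNA-1 were XIRP2, PADI2, CNRIP1, NDST3, DIRAS2, CD163, OPCML and GAP43, from 2.42 down to 1.65. PADI2, a peptidylarginine deiminase, rose from 9.85 ± 3.03 to 38.1 ± 2.16 CPM (1.96, SE 0.13, adjusted p = 1.17e-09) and OPCML, a cell adhesion molecule, by 1.67 (SE 0.13, adjusted p = 3.93e-09). The 8 with the largest fall were CHAC1, SDF2L1, HERPUD1, BANCR, HSP90B1, HSPA5, ALDH1L2 and DDIT3, from -1.97 to -1.37, of which BANCR was the long noncoding RNA (-1.49, SE 0.09, adjusted p = 1.99e-10). The calls of CD163 (0.80) and ALDH1L2 (-0.29) ended with scramble library 1 as the sole control. Of the 2370 called genes, 2245 had siRNA-1 and scramble libraries that did not overlap, against 28.8% of all genes tested and 10% by chance. Calling genes selects for such separation, so this count is no separate support for the calls, here and in the comparisons below. The count was 1513 without siRNA-1 library 1, 1491 without siRNA-1 library 2, 1545 without scramble library 2, 1421 without scramble library 3, 568 with scramble library 1 as the sole control and 2498 with scramble library 2.

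**Figure D2:**
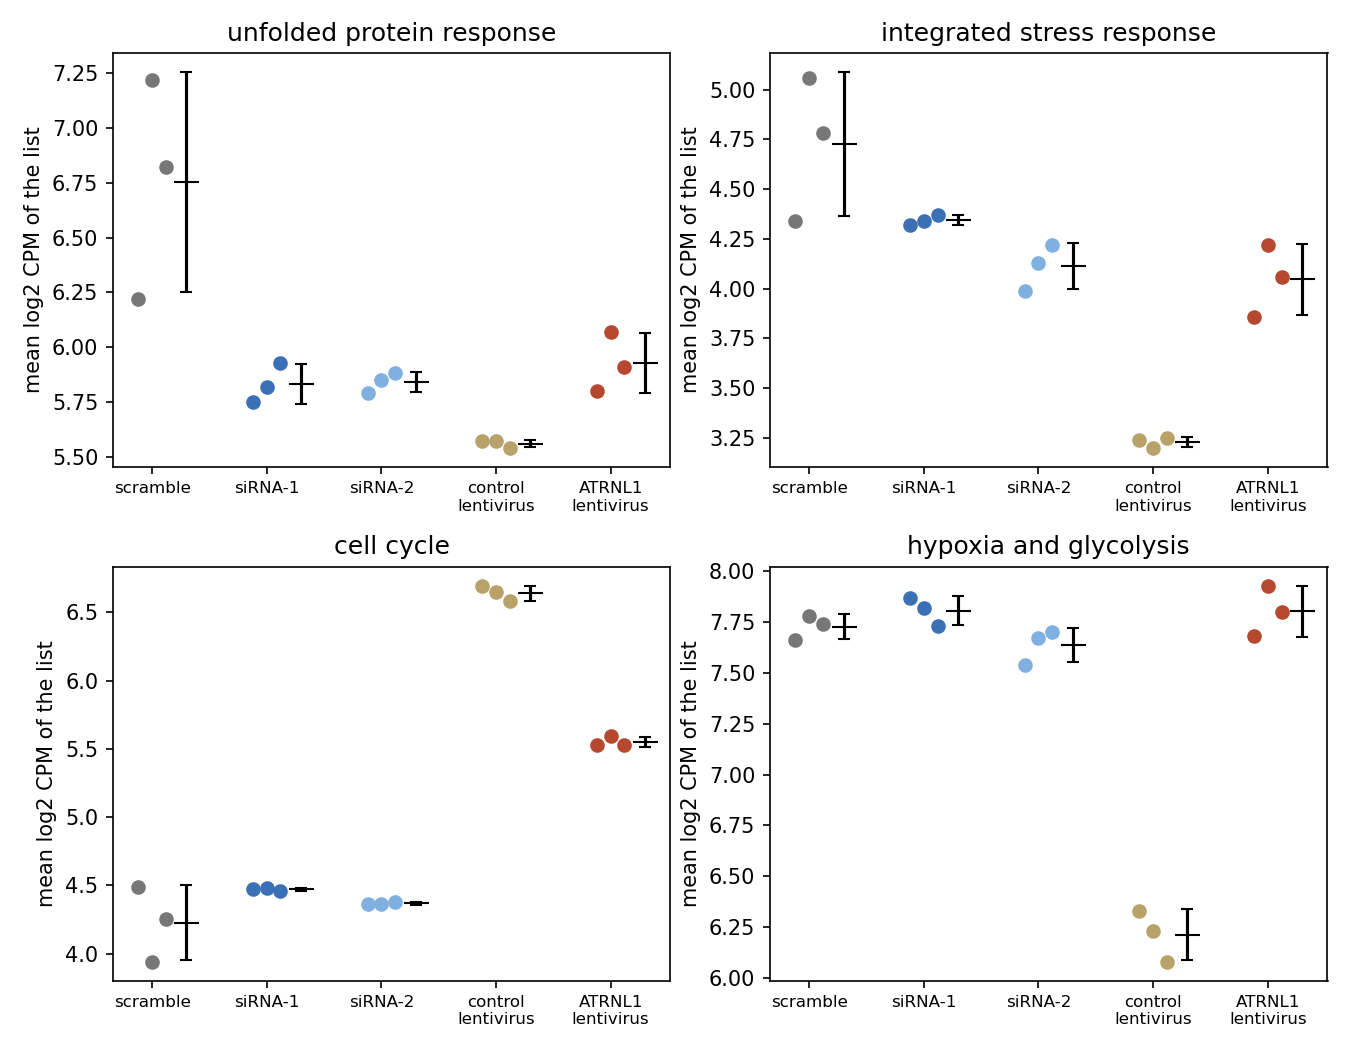
Mean log2 CPM of the genes of the unfolded protein response, integrated stress response, cell cycle and hypoxia lists in each of 15 libraries; points are libraries and bars the mean ± SD of 3 libraries per group. In the unfolded protein response panel the scramble libraries lay at 6.22, 7.22 and 6.82, above the siRNA-1 mean of 5.83 and the siRNA-2 mean of 5.84.

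siRNA-2, which lowered ATRNL1 further, was compared with scramble to see which changes a second sequence gave. Among chaperones of the endoplasmic reticulum HSPA5 fell again, to 553 ± 20.3 CPM (log2 fold change -1.50, SE 0.18, adjusted p = 1.09e-06), and CALR, the calcium-binding chaperone calreticulin, from 654 ± 179 to 210 CPM (-1.64, SE 0.12, adjusted p = 1.39e-09). SLC7A11, the cystine importer, fell from 16.3 to 4.06 CPM (-2.01, SE 0.14, adjusted p = 3.24e-10), and GJA1, the gap junction protein connexin 43, fell by 1.18 (SE 0.08, adjusted p = 1.52e-10). HSPA5 was at -0.72 with scramble library 1 as the sole control, and its SE again shares the spread of all 5 groups. CASQ2 rose by 1.91 (SE 0.13, adjusted p = 2.26e-10). A total of 2378 genes rose and 2092 fell, 553 of them by at least 1 on the log2 scale. Scaled by library size only, 3491 rose and 1486 fell.

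With siRNA-2, 18 of 22 genes of the unfolded protein response fell and 0 rose (21 fell adjusted over the list alone). Their median was -0.91 (camera adjusted p = 1.79e-18 and adjusted p = 0.445 with an estimated correlation). The scramble libraries, at 6.22, 7.22 and 6.82, were set against 5.84 ± 0.05, and with scramble library 1 as the sole control the median was -0.36 with 11 genes lower. Of the integrated stress response, 25 of 33 genes fell and 2 rose (29 and 2 adjusted over the list alone). Their median was -0.55 (camera adjusted p = 8.39e-14 and adjusted p = 0.445 with an estimated correlation), with scramble at 4.34, 5.06 and 4.78 against 4.11 ± 0.12 with siRNA-2, and against scramble library 1 alone the median was -0.11 with 4 genes lower. Among p53 targets 15 fell and 1 rose (16 and 1 adjusted over the list alone). The median was -0.27 (camera adjusted p = 1.93e-06 and adjusted p = 0.445 with an estimated correlation), with RRM2B at -0.80, and against scramble library 1 alone it was -0.13 with 2 genes lower. Heat shock genes held 9 of 20 that fell (10 adjusted over the list alone). The median was -0.22 (camera adjusted p = 0.000146 and adjusted p = 0.633 with an estimated correlation). Of 18 oxidative stress genes 8 fell (8 fell and 1 rose adjusted over the list alone). Their median was -0.19 (camera adjusted p = 0.000812 and adjusted p = 0.445 with an estimated correlation), with PRDX1 at -0.54. With scramble library 1 as the sole control the heat shock median was -0.03 and the call ended.

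With siRNA-2 cholesterol synthesis held 11 of 24 genes that fell and 2 that rose (12 and 2 adjusted over the list alone). Their median was -0.20 (camera adjusted p = 6.46e-05 and adjusted p = 0.445 with an estimated correlation), with MSMO1 at -0.76. Fatty acid synthesis held 7 of 15 that fell (7 fell and 1 rose adjusted over the list alone). The median was -0.14 (camera adjusted p = 0.000455 and adjusted p = 0.445 with an estimated correlation), with SCD at -0.82. Mean log2 CPM of fatty acid synthesis genes ran from 5.95 to 6.24 in the scramble libraries, against 5.93 ± 0.02 with siRNA-2. Nuclear oxidative phosphorylation genes held 10 of 40 that fell (14 adjusted over the list alone). The median was -0.14 (camera adjusted p = 8.01e-06 and adjusted p = 0.625 with an estimated correlation), with ATP5F1B at -0.58. In addition, 9 of 13 mitochondrially encoded genes fell (13 adjusted over the list alone). Their median was -0.51 (camera adjusted p = 8.01e-06 and adjusted p = 0.625 with an estimated correlation). Without siRNA-2 library 3 the list's median was -0.37 and 0 of the 13 genes were called singly, with MT-ND5 then at -0.41. Hypoxia and glycolysis genes held 8 of 28 that fell and 5 that rose (11 and 5 adjusted over the list alone). Their median was -0.14 (camera adjusted p = 0.0138 and adjusted p = 0.732 with an estimated correlation), with PGAM1 at -0.82 and NDRG1 at 0.76, and the list call ended without siRNA-2 library 1 (median -0.11) or with scramble library 1 as the sole control (-0.14). Ribosomal protein genes held 3 of 40 that fell (3 adjusted over the list alone, camera adjusted p = 0.00159 and adjusted p = 0.732 with an estimated correlation). Lysosome genes held 8 of 30 that fell and 3 that rose (11 and 3 adjusted over the list alone, camera adjusted p = 0.00801 and adjusted p = 0.633 with an estimated correlation), a call that ended without scramble library 2 (median -0.06) or with scramble library 1 as the sole control (-0.02).

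Sarcomere genes held 10 of 28 that rose with siRNA-2 and 1 that fell (11 and 4 adjusted over the list alone). The median was 0.13 (camera adjusted p = 0.00324 and adjusted p = 0.732 with an estimated correlation), with MYH7 at 0.83. Action potential ion channels held 10 of 32 that rose and 2 that fell (11 and 4 adjusted over the list alone). The median was 0.03 (camera adjusted p = 0.045 and adjusted p = 0.732 with an estimated correlation), with KCNJ8, an ATP-sensitive potassium channel subunit, at 1.23. Smooth muscle markers held 5 of 12 that rose (5 adjusted over the list alone). Their median was 0.22 (camera adjusted p = 0.00231 and adjusted p = 0.625 with an estimated correlation), with CNN1 at 0.91. Neural markers held 3 of 7 that rose (5 adjusted over the list alone). Their median was 0.55 (camera adjusted p = 0.00242 and adjusted p = 0.445 with an estimated correlation). Cell cycle genes held 8 of 38 that rose and 1 that fell (8 and 1 adjusted over the list alone). The median was 0.08 (camera adjusted p = 0.00852 and adjusted p = 0.732 with an estimated correlation). Histones held 4 of 26 that rose and 2 that fell (4 and 2 adjusted over the list alone). The median was 0.20 (camera adjusted p = 0.0138 and adjusted p = 0.732 with an estimated correlation), beside scramble levels of 4.49, 3.94 and 4.25 for cell cycle and 3.29, 2.44 and 3.00 for histones. Genes of the attractin family and partners held 3 of 10 that fell (3 adjusted over the list alone). Their median was -0.07 (camera adjusted p = 0.0348 and adjusted p = 0.445 with an estimated correlation), and ATRNL1 and ATRN were among those that fell. ATRNL1 is the target of the siRNAs, so this list call is not independent of the knockdown. Without scramble library 2 the calls of sarcomere (median 0.03), ion channels (0.05), smooth muscle (0.05), cell cycle (-0.05), histones (0.05) and the attractin family (0.05) ended. The medians turned to -0.09 for sarcomere, -0.02 for ion channels, -0.14 for smooth muscle, -0.18 for cell cycle and -0.17 for histones with scramble library 1 as the sole control. The attractin call also ended without siRNA-2 library 3 (-0.08), its median turned to 0.02 without siRNA-2 library 2, and the ion channel call without siRNA-2 library 2 (0.04).

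The largest rises after siRNA-2 included IL31RA, a cytokine receptor subunit (3.01, SE 0.29, adjusted p = 4.4e-08), MXRA5, a matrix protein (7.43 to 45.5 CPM, 2.62, SE 0.20), ADGRL4 (2.61, SE 0.23), ASTN1 (2.42, SE 0.23), SULT1E1 (2.25, SE 0.17), GIPC3 (2.07, SE 0.21) and MYOM3 (2.01, SE 0.20), and the largest falls CHAC1 (-2.09, SE 0.17), SLC7A11, SDF2L1 (-1.80, SE 0.23), CALR and SERPINI1, which encodes neuroserpin (127 ± 0.578 to 41 ± 2.52 CPM, -1.63, SE 0.09, adjusted p = 2.56e-11). Scramble levels were widely spread for IL31RA (0.927 ± 0.519 CPM, SD, n = 3), MXRA5 (7.43 ± 3.17 CPM) and ADGRL4 (0.671 ± 0.326 CPM), but not for SERPINI1. Several lists were not called in either siRNA comparison. With siRNA-2, ventricular identity held 4 of 13 that rose and 2 that fell (4 and 4 adjusted over the list alone), calcium handling 6 and 2 of 26 (7 and 3 adjusted over the list alone), intercalated disc genes 5 and 5 of 18 (7 and 6 adjusted over the list alone), natriuretic and hypertrophy genes 4 and 2 of 13 (4 and 3 adjusted over the list alone, median -0.18, mean 0.08), apoptosis genes 2 and 2 of 22 (the same adjusted over the list alone), interferon genes 7 and 2 of 34 (the same adjusted over the list alone) and matrix genes 8 and 3 of 34 (9 and 3 adjusted over the list alone). Fatty acid oxidation held 3 of 25 that rose and 3 that fell (4 and 4 adjusted over the list alone), NF-kB genes 1 and 0 of 14, NOTCH, WNT and hedgehog targets 3 and 0 of 21 and fibroblast markers 3 and 0 of 12 (each the same adjusted over the list alone). Of 4470 called genes, 4274 had siRNA-2 and scramble libraries that did not overlap, against 36.7% of all genes and 10% by chance. The count was 1803 with scramble library 1 and 3513 with scramble library 2 as the sole control.

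The overlap of both siRNAs asked which changes did not depend on 1 siRNA sequence. The genes lowered by both included 18 of the unfolded protein response, 12 of the integrated stress response, 11 p53 targets and 10 of cholesterol synthesis, and those raised by both 7 sarcomere, 7 atrial fibrillation locus and 6 cell cycle genes. Against scramble library 1 alone the list medians with siRNA-1 and siRNA-2 were -0.09 and -0.09 for sarcomere, 0.01 and -0.07 for atrial fibrillation loci and -0.01 and -0.18 for cell cycle. Of the lowered lists, the integrated stress response was then at 0.15 and -0.11, the unfolded protein response at -0.36 and -0.36, p53 targets at -0.22 and -0.13 and cholesterol synthesis at -0.35 and -0.22. Of the 10 genes named by rule in each direction, those that rose and reached 1 CPM in some group were XKR4 (2.99 and 2.58), PADI2 (1.96 and 2.02), XIRP2 (2.42 and 1.93), ANKRD34C (1.79 and 2.68) and NDST3 (1.84 and 1.78). XKR4 stood at 0.228 CPM in scramble, 1.77 with siRNA-1 and 1.33 with siRNA-2. Those that fell included CHAC1 (-1.97 and -2.09), SDF2L1 (-1.96 and -1.80) and HSP90B1 (-1.43 and -1.47). ENSG00000261270 and ENSG00000261114, also among the falls and annotated as sense intronic, overlap the HERPUD1 locus, so their reads may be those of HERPUD1. In number, 916 genes rose and 513 fell with both siRNAs and 44 changed in opposite directions. Independent lists would share 139.2 rises and 78.6 falls, and unchanged groups simulated against the same scramble libraries shared 0 in each of 10 draws. That simulation drew genes independently with 1 spread for all groups, so it leaves out shifts common to many genes in a scramble library. Scramble libraries 1 and 2 differed by an SD of 0.238 on the log2 scale, against at most 0.128 within siRNA-1 and 0.095 within siRNA-2. Put in the place of the control, the siRNA-1 libraries gave 1542 genes changed the same way. Across genes, which are not independent replicates, the fold changes correlated at r = 0.579 with a covariance of 0.098, against r = 0.466 and a covariance of 0.038 in the simulation, and at r = 0.138 to 0.379 when each siRNA was set against a different single scramble library. The 1429 genes changed the same way were 1887 without scramble library 1, 931 without library 2 and 879 without library 3, and with a sole control they were 336 for scramble library 1 and 1712 for scramble library 2. The fits against all scramble libraries, library 1 alone and library 2 alone shared 200 of these genes.

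The direct comparison of siRNA-1 with siRNA-2 asked where the 2 sequences differed. Relative to siRNA-2, siRNA-1 cells had more GJA1 (1.18, SE 0.08, adjusted p = 4.54e-10), SERPINI1 (1.57, SE 0.09, adjusted p = 9.7e-11) and SLC7A11 (1.23, SE 0.14, adjusted p = 1.79e-06). SERPINI1 stood at 122 ± 0.187 CPM with siRNA-1 and 41 ± 2.52 CPM with siRNA-2. Heat shock, mitochondrially encoded and ribosomal protein genes were higher with siRNA-1 by camera at the preset correlation, and cholesterol synthesis genes lower. None of these list calls held with an estimated correlation (adjusted p = 0.96 with an estimated correlation for each). In total 1382 genes were higher and 1117 lower with siRNA-1, 188 of them by at least 1 on the log2 scale. Scaled by library size only, 1045 were higher and 2055 lower.

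The camera values that follow are those at the preset correlation, and each of the 13 called lists had an adjusted p = 0.96 with an estimated correlation. Higher with siRNA-1 were 12 of 13 mitochondrially encoded genes (13 adjusted over the list alone; median 0.59, camera adjusted p = 2.6e-09). Their mean log2 CPM was 11.99, 11.70 and 11.17 in the siRNA-1 libraries and 11.14, 11.18 and 10.73 in the siRNA-2 libraries, so siRNA-1 library 3 lay at the level of siRNA-2 library 2. Without siRNA-1 library 1 the median was 0.42 with 1 gene higher, without siRNA-1 library 2 it was 0.57 with 5 higher, and without siRNA-2 library 3 it was 0.50 with 1 higher. The share of counts from mitochondrial genes was 6.69% ± 1.26 with siRNA-1, 4.94% ± 0.592 with siRNA-2 and 6.48% ± 0.266 with scramble (SD, n = 3). Also higher with siRNA-1 were 10 of 20 heat shock genes (15 adjusted over the list alone; median 0.31, camera adjusted p = 7.55e-09), with HSP90AA1 at 0.57, 9 of 40 ribosomal protein genes (20 adjusted over the list alone; median 0.18, camera adjusted p = 4.89e-11), with RPS25 at 0.55, 9 of 33 integrated stress response genes (12 higher and 1 lower adjusted over the list alone; median 0.25, camera adjusted p = 0.000166) and 9 of 28 hypoxia and glycolysis genes (11 adjusted over the list alone; median 0.17, camera adjusted p = 3.91e-05), with ENO1 at 0.58. Lower with siRNA-1 were 9 of 24 cholesterol synthesis genes, with 2 higher (12 and 2 adjusted over the list alone; median -0.20, camera adjusted p = 5.29e-07), 9 of 34 matrix genes, with 3 higher (14 and 6 adjusted over the list alone; median -0.21, camera adjusted p = 0.00813), among them COL6A2 at -0.68, 4 of 12 smooth muscle markers, with 1 higher (5 and 1 adjusted over the list alone; median -0.37, camera adjusted p = 0.00203), and 6 of 34 interferon genes, with 3 higher (9 and 3 adjusted over the list alone; median -0.17, camera adjusted p = 0.0388). Cell cycle genes (4 higher, 1 lower; 6 and 2 adjusted over the list alone, camera adjusted p = 0.0139), atrial identity (5 and 1; 8 and 3 adjusted over the list alone, camera adjusted p = 0.0139), cardiac transcription factors (5 and 0; 7 and 0 adjusted over the list alone, camera adjusted p = 0.0385) and nuclear oxidative phosphorylation genes (3 and 1; the same adjusted over the list alone, camera adjusted p = 0.0309) completed the 13 called lists. The medians of cardiac transcription factors (0.06) and oxidative phosphorylation genes (0.04) turned to -0.01 and -0.03 when libraries were scaled by size only, where the interferon call also ended (-0.24). Leaving out 1 library ended the call of cardiac transcription factors without siRNA-1 library 1 (0.03) or 2 (0.06) or siRNA-2 library 1 (0.05), that of oxidative phosphorylation without siRNA-1 library 1 or siRNA-2 library 1 (0.03 each), and that of matrix genes without siRNA-1 library 3 (-0.10). The interferon call ended without siRNA-1 library 1 (-0.18) or 2 (-0.08) and without siRNA-2 library 1 (-0.11), 2 (-0.09) or 3 (-0.18). The unfolded protein response did not pass the test, with 1 of 22 genes higher, a median of 0.00 and a camera adjusted p = 0.876 (adjusted p = 0.997 with an estimated correlation).

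The 4 genes named in each direction between the siRNAs lay below 1 CPM in every group, with SLC6A2 at 1.86 (SE 0.34, adjusted p = 0.00061) and CYP17A1 at -3.03 (SE 0.50, adjusted p = 0.00016). The groups did not overlap in 2480 of the 2499 called genes, against 33.9% of all genes and 10% by chance. The count of 2499 was 1664 without siRNA-1 library 1, 1498 without siRNA-1 library 2, 1432 without siRNA-2 library 2, 1582 without siRNA-2 library 3, and 4914 when only these groups entered the fit.

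The comparison of the ATRNL1 lentivirus with the control lentivirus asked which genes changed when the short isoform of ATRNL1 was raised. Cell cycle genes were lower (adjusted p = 0.173 with an estimated correlation) and genes of hypoxia and glycolysis higher (adjusted p = 0.163 with an estimated correlation), calls by camera at the preset correlation. RRM2, a subunit of ribonucleotide reductase, fell from 161 to 36.1 CPM (log2 fold change -2.16, SE 0.19, adjusted p = 9.41e-10), and TXNIP, an inhibitor of glucose uptake, from 271 ± 13.9 to 20.0 ± 0.635 CPM (-3.76, SE 0.11, adjusted p = 1.14e-17). NDRG1, a hypoxia-induced gene, rose from 2.43 to 69.2 CPM (4.80, SE 0.17, adjusted p = 1.49e-16) and VEGFA, the vascular growth factor, by 2.15 (SE 0.09, adjusted p = 3.75e-15). In the scramble siRNA cells NDRG1 stood at 28.8, TXNIP at 5.58 and RRM2 at 9.65 CPM. In all 4715 genes rose and 4434 fell, 1996 of them by at least 1 on the log2 scale.

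With overexpression 38 of 38 cell cycle genes fell (38 adjusted over the list alone). Their median was -1.06 (camera adjusted p = 8.69e-34 and adjusted p = 0.173 with an estimated correlation), with CDC6 at -1.93, MCM6 at -1.61 and PCNA at -1.49. Among histones 24 of 26 genes fell (24 adjusted over the list alone). The median was -1.16 (camera adjusted p = 8.15e-18 and adjusted p = 0.318 with an estimated correlation). Of 28 hypoxia and glycolysis genes 27 rose (27 adjusted over the list alone). The median was 1.3 (camera adjusted p = 1.52e-31 and adjusted p = 0.163 with an estimated correlation), with ENO1 at 1.98. Of the integrated stress response 26 of 33 rose and 1 fell (27 and 1 adjusted over the list alone). Their median was 0.71 (camera adjusted p = 8.15e-09 and adjusted p = 0.651 with an estimated correlation), with the secreted glycoprotein STC2 at 2.46 and DDIT3 at 1.72 (SE 0.19). The unfolded protein response held 12 of 22 that rose and 0 that fell (14 and 1 adjusted over the list alone). Their median was 0.46 (camera adjusted p = 0.0116 and adjusted p = 0.827 with an estimated correlation), with HERPUD1 at 1.54 (SE 0.18) and HSPA5 at 0.76 (SE 0.18, adjusted p = 0.00117). That list call ended without ATRNL1 lentivirus library 2, where the median was 0.35 and 8 genes rose, and with a filter of 1 CPM in 3 libraries, where it was 0.47. Immediate early genes held 13 of 23 that rose and 2 that fell (13 and 2 adjusted over the list alone). The median was 1.02 (camera adjusted p = 3.68e-06 and adjusted p = 0.651 with an estimated correlation), with NR4A3 at 2.7 and EGR1 at 2.15. Cholesterol synthesis held 14 of 24 that rose and 2 that fell (16 and 2 adjusted over the list alone). The median was 0.45 (camera adjusted p = 2.21e-05 and adjusted p = 0.42 with an estimated correlation), with INSIG1 at 1.56.

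Among cardiac lists, 12 of 13 ventricular identity genes rose with overexpression and 1 fell (12 and 1 adjusted over the list alone). Their median was 0.75 (camera adjusted p = 1.03e-06 and adjusted p = 0.318 with an estimated correlation), with LBH at 1.2, MYL2, the ventricular myosin light chain, at 0.88, and GJA1 at 0.85. Cardiac transcription factors held 17 of 24 that rose and 4 that fell (18 and 4 adjusted over the list alone). Their median was 0.31 (camera adjusted p = 0.00019 and adjusted p = 0.658 with an estimated correlation), with PPARA at 0.99. Ion channels held 13 of 32 that rose and 3 that fell (14 and 3 adjusted over the list alone). The median was 0.24 (camera adjusted p = 0.00733 and adjusted p = 0.658 with an estimated correlation), with the sulfonylurea receptor ABCC9 at 1.34. Matrix genes held 22 of 34 that rose and 3 that fell (23 and 4 adjusted over the list alone). The median was 0.36 (camera adjusted p = 0.000429 and adjusted p = 0.755 with an estimated correlation). Lysosome genes held 13 of 30 that rose and 1 that fell (13 and 1 adjusted over the list alone). Their median was 0.17 (camera adjusted p = 0.019 and adjusted p = 0.755 with an estimated correlation). Atrial identity genes held 3 that rose and 11 that fell of 22 (4 and 11 adjusted over the list alone), with a median of -0.21 and a camera adjusted p = 0.0742 (adjusted p = 0.827 with an estimated correlation). The lysosome call ended without ATRNL1 lentivirus library 2 (median 0.11) and with a filter of 1 CPM in 3 libraries (0.14). Markers of these other cell types did not pass the test as lists, with 3 of 6 endothelial markers that rose and 1 that fell, 2 and 5 of 13 epicardial, 1 and 1 of 12 endoderm and liver, 0 and 1 of 5 pluripotent and 3 and 1 of 7 skeletal muscle (3 and 1, 3 and 6, 1 and 1, 0 and 1, and 3 and 1 adjusted over the list alone), although the skeletal muscle troponin TNNT3 rose by 4.11.

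The named rises with overexpression, besides ATRNL1 and NDRG1, were CACNA1I, a calcium channel subunit (5.63, SE 0.27), NDUFA4L2 (4.97, SE 0.20), SNCB (4.90, SE 0.26), TGFA (4.74, SE 0.27), CREG2 (4.36, SE 0.19) and SV2B (4.13, SE 0.24). The falls were TXNIP, SYT10 (-3.28, SE 0.33), SERTM2 (-2.30, SE 0.20), the cell cycle transcription factor E2F2 (-2.22, SE 0.12), RRM2, MBNL3 (-2.09, SE 0.13), TEX15 (-2.09, SE 0.34) and FAM111B (-2.08, SE 0.19). Of 9149 called genes, 8479 had groups that did not overlap, against 42.9% of all genes and 10% by chance. None of the 12 list calls held with an estimated correlation.

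**Figure D3:**
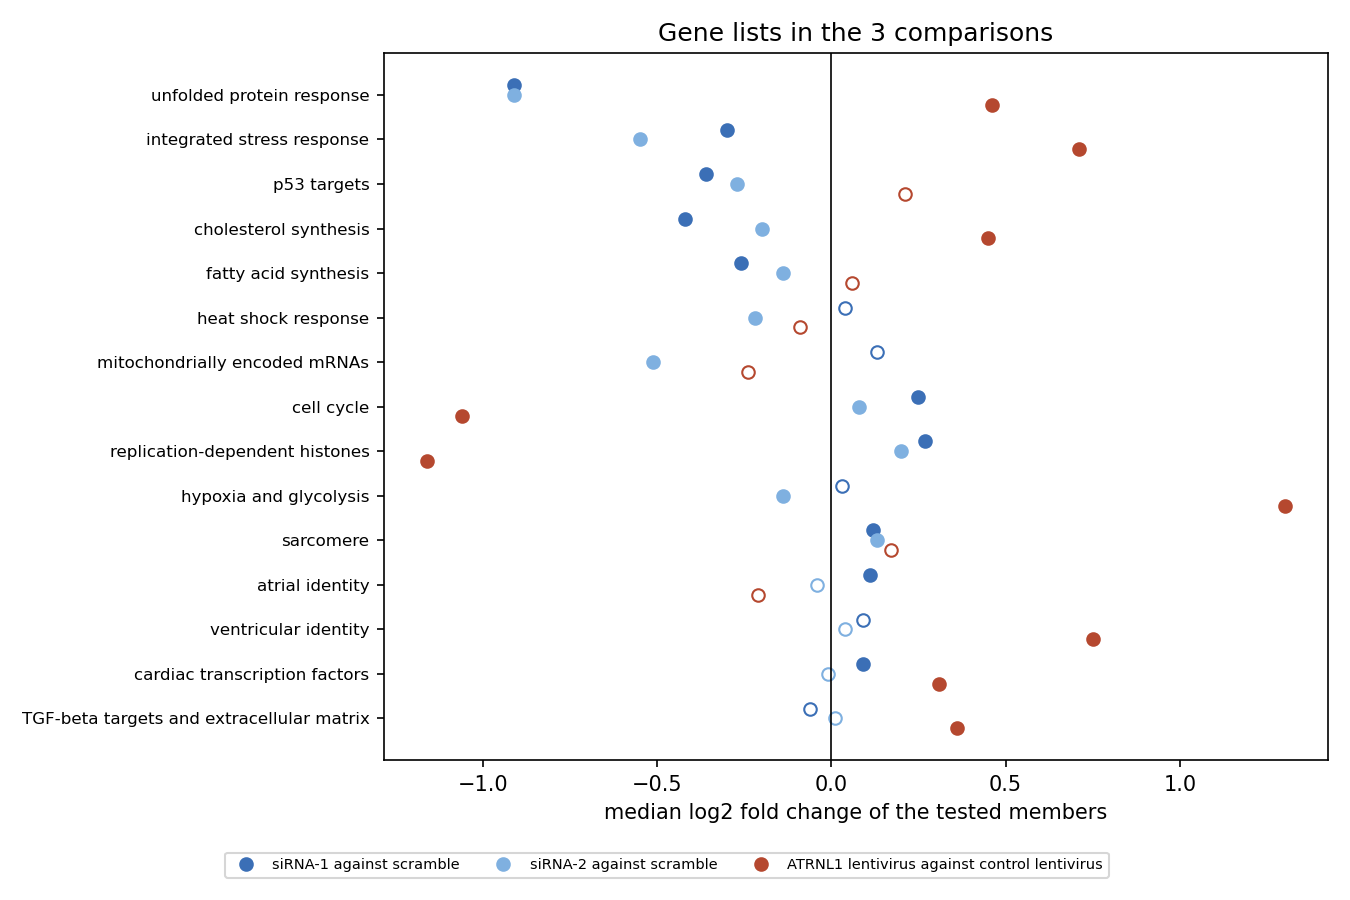
Median log2 fold change of 15 gene lists in siRNA-1 against scramble, siRNA-2 against scramble and ATRNL1 lentivirus against control lentivirus; filled points passed camera at the preset correlation and open points did not. The unfolded protein response lay at -0.91 with each siRNA and 0.46 with overexpression, and cell cycle genes at 0.25, 0.08 and -1.06.

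Knockdown and overexpression were set side by side to see which genes moved in opposite directions. The mean of both siRNAs against scramble called 2113 rises and 1755 falls, or 2705 and 1428 scaled by library size only. Among the genes lower with knockdown and higher with overexpression were 12 of the unfolded protein response, 18 of the integrated stress response and 12 of cholesterol synthesis, and among those higher and then lower 11 cell cycle genes, 6 interferon and 5 histone genes. Mean log2 CPM of the unfolded protein response was 6.75 in scramble and 5.83 and 5.84 with siRNA-1 and siRNA-2. It was 5.56 with the control lentivirus and 5.93 with overexpression. For the integrated stress response the 5 levels were 4.73, 4.34, 4.11, 3.23 and 4.05. In level, overexpressing cells thus lay near the knockdown cells, while the controls differed. The lentiviral and siRNA groups also differ in delivery. These levels therefore cannot tell whether the opposite directions come from ATRNL1 or from the controls. Scramble library 1 stood at 4.34 in the integrated stress response, level with siRNA-1. HERPUD1 was at -1.48 (SE 0.15, adjusted p = 1.19e-07) with knockdown and 1.54 with overexpression, DDIT3 at -1.42 and 1.72, ALDH1L2 at -1.47 (-0.36 and not called with scramble library 1 as the sole control) and 1.51, and CHAC1 at -2.03 and 1.58. KIT, a receptor tyrosine kinase, rose in both, by 1.57 (SE 0.13) and 1.77 (SE 0.13), as did GADL1 (1.58 and 1.79), CNTN3 (1.46 and 1.57) and GIPC3 (1.46 and 1.43). Of 2221 genes called in both, 648 were up and then down, 546 down and then up, 618 up in both and 409 down in both, where independent lists would share 379.9, 335.6, 404.0 and 315.6. Across genes the fold changes correlated at r = -0.002 and rho = -0.017.

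The test of the difference between the overexpression and knockdown effects called 7879 genes, 4066 with the higher value in overexpression and 3813 with the lower. By that test 19 of 22 unfolded protein response genes were higher (19 adjusted over the list alone). Their median was 1.2 (camera adjusted p = 6.47e-12 and adjusted p = 0.477 with an estimated correlation). Of 33 integrated stress response genes 28 were higher (29 adjusted over the list alone). The median was 1.10 (camera adjusted p = 4.8e-15 and adjusted p = 0.477 with an estimated correlation). Of 24 cholesterol synthesis genes 17 were higher and 2 lower (18 and 3 adjusted over the list alone). The median was 0.75 (camera adjusted p = 3.83e-10 and adjusted p = 0.141 with an estimated correlation). All 38 cell cycle genes were lower (38 adjusted over the list alone). Their median was -1.19 (camera adjusted p = 7.92e-34 and adjusted p = 0.141 with an estimated correlation). The knockdown count of 3868 was 2464 without scramble library 2, 2311 without scramble library 3, 1000 with scramble library 1 as the sole control and 3040 with scramble library 2.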

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

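The tests of explanations and the splits of the libraries given here were chosen after the results were seen, whereas the comparisons they bear on were planned.

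siRNA-1 and siRNA-2 differed in 2499 genes by the test of the difference between them, with SERPINI1 and GJA1 among the clearest. The 10 splits of these 6 libraries are too few for a share under 0.05, and the highest of the others called 0 genes. Another 44 genes were called against scramble in opposite directions with siRNA-1 and siRNA-2, 30 up and then down and 14 down and then up. The overexpression effect differed from the mean knockdown effect in 7879 genes. Of 100 splits of all 15 libraries 2 gave as many, the real one included. That share excludes libraries without group structure. It cannot test the difference itself, since the splits also mixed lentiviral with siRNA libraries. The highest of the others gave 10126 and was the split that parted the control lentivirus libraries from the rest, which points to a structure of the samples.

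The first pattern weighed was the fall of the unfolded protein response and the rise of cell cycle genes with both siRNAs, set beside scramble libraries that differed among themselves. Scramble library 2 as the whole cause was excluded for the unfolded protein response, whose median was still -0.36 with scramble library 1 as the sole control. The fall shrank with that control, since the list stood at 6.22 in library 1 and at 6.75 in the scramble mean. For cell cycle genes the same control left a median of -0.01 with siRNA-1, so library 2 may account for their rise. Against a fall in proportion to ATRNL1, the siRNAs differed by 0.00 (SE 0.06) in the list's mean. The ratio of their ATRNL1 changes, 2.18, asks for 0.68. That 0.68 rests on the scramble mean, whose spread the SE leaves out, and would be smaller from scramble library 1. The test therefore argues against proportion but does not exclude it. A response that is full at the weaker knockdown, an effect of the scramble siRNA itself and an effect of either siRNA on other genes stay open as untested, since the design holds no untransfected cells. Scramble was the group that stood apart in this list, with a mean log2 CPM of 6.75 against 5.56 to 5.93 in the others. The lentiviral groups among these also differ in delivery.

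Against scramble the real split called 2370 genes with siRNA-1 and the highest other 2, and 4470 with siRNA-2 and the highest other 0, where 10 splits are too few for a share under 0.05. For the mean of both siRNAs 1 of 100 splits, the real one, gave 3868 genes or more. The split with the siRNA-1 libraries in the place of the control gave 3835. For genes changed the same way by both siRNAs 2 of 100 splits gave 1429 or more, and that same split gave 1542. These shares exclude libraries without group structure, but do not set scramble apart from siRNA-1 as the shared control.

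The second pattern was that overexpression ran against the effect of the control lentivirus. Control lentivirus cells had 37 of 38 cell cycle genes above scramble, with a median of 2.61, and 26 of 28 hypoxia and glycolysis genes below, with a median of -1.70, and the ATRNL1 lentivirus moved both lists back toward scramble. Of 7639 genes called in both comparisons 6808 went opposite ways, against 2912 for independent lists, and r was -0.649, against -0.506 for unchanged groups simulated with the same control libraries. Noise of single control libraries was excluded as the whole cause. With different control lentivirus libraries in the 2 comparisons the covariance was -0.344 or further below 0, against -0.041 in the simulation. There r was -0.547 to -0.456. What all control lentivirus libraries had in common still entered both comparisons, so this test cannot exclude it. Knockdown and overexpression fold changes showed no opposite trend across all genes, with correlations between -0.066 and 0.058 as libraries were left out in turn. That does not exclude opposite effects of less and more ATRNL1, since the overexpression effect is confounded with the lentiviral cultures. A difference between the lentiviral cultures in virus dose, selection or growth cannot be told apart from an effect of ATRNL1, since virus and group are confounded. For overexpression the real split called 9149 genes and the highest other 0, where 10 splits are too few for a share under 0.05.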

How the results depend on the processing

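A fit without the library of each group most like a mix of the others and fits with a single scramble library as control were chosen after the data were seen. The other alternatives were planned. The planned fit without the joined-number libraries was not run, because columns could not be tied to samples. No paired analysis was possible because the labels give the groups no shared replicate numbers. Where 1 library was left as control, it was assumed to vary like the other groups. For the unfolded protein response the SD of the list mean was 0.50 in scramble and 0.02 to 0.14 in the other groups. Calls from these fits therefore use too small a spread for such genes.

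Requiring a log2 change of at least 1 left 241 genes with siRNA-1, 553 with siRNA-2, 346 for their mean, 131 for both in the same direction, 188 between the siRNAs, 1996 with overexpression and 2250 between overexpression and knockdown, fewer by construction. Without the library of each group most like a mix the counts were 511 with siRNA-1, 1557 with siRNA-2, 1094 for their mean, 305 for both, 538 between the siRNAs and 4872 between overexpression and knockdown, from fewer samples. With scramble library 1 as the sole control they were 568, 1803, 1000 and 336 for the first 4 of these and 4886 for the last, and with scramble library 2 as the sole control 2498, 3513, 3040, 1712 and 7089. Leaving out 1 library at a time gave 1421 to 2984 genes with siRNA-1, 3113 to 4591 with siRNA-2, 2311 to 4104 for their mean, 879 to 1887 for both, 1432 to 1700 between the siRNAs, 7715 to 9345 with overexpression and 6820 to 8506 between overexpression and knockdown. A fit of the 2 siRNA groups alone called 4914 genes between them, and the cause was not tested. ATRNL1 kept its direction and call in each refit, but its changes of -0.74 with siRNA-1 and 0.87 between the siRNAs lie under a log2 change of 1. Single-gene results were also followed without the library of each group most like a mix. Of these, 324 kept direction and call and 137 lost the call.

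Scaling by library size only moved the split of rises and falls to 3491 and 1486 with siRNA-2, 2705 and 1428 for the mean of both siRNAs, and 1045 and 2055 between the siRNAs, with median shifts of all genes of 0.07, 0.03 and -0.07. It turned the medians of cardiac transcription factors to -0.01 and of nuclear-encoded oxidative phosphorylation to -0.03 between the siRNAs.

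Of the called lists, an estimated correlation left 1 of 17 with siRNA-1, 0 of 19 with siRNA-2, 0 of 13 between the siRNAs and 0 of 12 with overexpression. The siRNA-1 lists called were 10 with scramble library 1 and 27 with scramble library 2 as the sole control, and 12 to 25 as libraries were left out. The siRNA-2 lists called were 12 to 24 as libraries were left out, and those between the siRNAs 8 with a filter of 1 CPM in 3 libraries. With scramble library 1 as the sole control the siRNA-1 medians turned to -0.09 for sarcomere, -0.05 for atrial identity, 0.15 for the integrated stress response, -0.01 for cell cycle and -0.10 for histones. The siRNA-2 medians turned to -0.09 for sarcomere, -0.02 for ion channels, -0.18 for cell cycle, -0.17 for histones and -0.14 for smooth muscle markers. Leaving out 1 library gave siRNA-2 medians of -0.19 to 0.05 for the attractin family and -0.05 to 0.20 for cell cycle. With scramble library 2 as the sole control RGS5 turned to 0.013 with siRNA-1. For these reversals the cause was not tested beyond the levels of the scramble libraries. On simulated counts at this depth 6 of 50 genes changed 1.2-fold were recovered with siRNA-1, so smaller changes than that were mostly out of reach.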

Other observations

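The comparison of the control lentivirus with scramble was added after the data were seen, and the test of mixed libraries was chosen before its result.

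Cells with the control lentivirus differed from scramble cells in 15675 genes, 7480 higher and 8195 lower, of which 7356 differed by at least 1 on the log2 scale. Virus, selection and siRNA transfection all differ between these groups. Proliferation genes were higher, with 37 of 38 cell cycle genes (median 2.61, camera adjusted p = 2.92e-25; adjusted p = 0.466 with an estimated correlation) and 26 of 26 histone genes (median 1.61). RRM2 stood at 161 CPM against 9.65 CPM in scramble. Stress and glycolysis genes were lower, with 19 of 22 unfolded protein response genes lower and 1 higher (median -1.06, camera adjusted p = 6.95e-05; adjusted p = 0.691 with an estimated correlation), 27 of 33 integrated stress response genes lower and 2 higher (median -1.49) and 26 of 28 hypoxia and glycolysis genes lower (median -1.70, camera adjusted p = 5.42e-12; adjusted p = 0.601 with an estimated correlation). Among 25 p53 targets 19 were lower and 3 higher (median -0.59), and 6 of 7 skeletal muscle markers were lower (median -1.43). ATRNL1 was higher with the control lentivirus, at 28.0 ± 1.11 against 15.3 ± 1.52 CPM (0.87, SE 0.11, adjusted p = 8.53e-08).

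In 4 groups the labels give 1 library a number that joins the numbers of the 2 others, as a mix of them would be named. A mix should lie between the other 2 in most genes, and the column that did so most often was between them in 52.1% of genes above 20 CPM with siRNA-1, 41.6% with siRNA-2, 55.9% with the control lentivirus and 44.0% with the ATRNL1 lentivirus, against 84.9% for a simulated mix and 33.3% for independent libraries. In scramble, which has no such number, library 3 was between the others in 74.0% of genes. There the other 2 differed by an SD of 0.238 on the log2 scale, against 0.095 to 0.169 in the 4 groups. The 84.9% was not simulated for each group and need not hold where libraries differ less. Of the 4 groups 0 exceeded the 74.0% of scramble. A ratio set the summed SDs from a library to the other 2 over the SD between those 2. It was 1.0 for a simulated mix and 2.01 for independent libraries. The same columns gave 1.17 with siRNA-1, 1.25 with the control lentivirus, 1.63 with siRNA-2 and 1.66 with the ATRNL1 lentivirus. Scramble library 3 gave 1.04. By this ratio siRNA-1 and the control lentivirus lay nearer to a mix. Since the columns could not be tied to the numbered samples, the mix cannot be told apart from 3 separate libraries.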
